A study of Mus musculus with 6 samples.

How the data were processed

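RNA abundance was measured with Affymetrix expression arrays in 6 cultures of mouse mesenchymal stem cells, the multipotent stromal cells that can become fat, bone or cartilage cells. Per the labels' protocols, total RNA was taken directly after exposure, and 200 ng was labelled with biotin by priming from the poly(A) tail. The deposited values are 1 log2 level per probe set and array, made by the authors with RMA, affy and limma per the submitters' processing notes, which give no versions or roles. RMA corrects background, normalizes quantiles between arrays and summarizes the probes of a set on a log2 scale. The log base is not written with the values and was taken to be 2 because RMA gives that scale. Values are rounded to 2 decimals, and the lower quartiles, medians and upper quartiles of the 6 arrays lie between 3.4 and 3.43, 4.82 and 4.87, and 7.44 and 7.49. Because normalization equalizes the arrays, a change shared by all transcripts cannot be seen, and all changes are relative to the other transcripts. The scanner files were not used here, so background correction and normalization could not be repeated from probe intensities.

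The values cover 45101 probe sets. The 64 Affymetrix control probe sets were left out of the tests, which leaves 45037. Genes were named from the platform annotation. Of the tested probe sets, 34945 have exactly 1 gene symbol, 932 have several and 9160 are unnamed here. The single-gene probe sets stand for 18194 genes. Symbols were checked through Entrez identifiers against a RefSeq gene table of the mouse assembly GRCm38.p6, which replaced 0 symbols and lacks the identifier of 204 of the single-gene probe sets. For lists, each gene was represented by its single-gene probe set with the highest mean level over the 6 arrays.

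The 6 arrays form 3 pairs, since per the series design each of 3 independent experiments held 1 irradiated culture and 1 adjacent control. Deviations of the paired arrays from their group means correlated across probe sets with r = 0.63, 0.14 and 0.50 in experiments 1, 2 and 3. Irradiated culture 2 correlated slightly better with control 3 (r = 0.15) than with its own control. The pairing was taken from the series design, and genes are not independent replicates in these correlations.

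Irradiated minus control log2 levels were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with the experiment as a fixed block. The tests were two-sided and Benjamini-Hochberg adjusted over the 45037 probe sets, with a threshold of 0.05 and no filter on dim probe sets. Intervals are 95% intervals from the same fit. The number of arrays, 3 per group, limits the precision. The median standard error of a log2 change is 0.088. On values simulated from these arrays with 200 of the probe sets changed by known amounts in each of 10 draws, this test recovered 18.7% of 1.5-fold, 86.4% of 2-fold and 99.8% of 4-fold changes, with 6.7 false calls per draw. Planting many changes at once loosens the adjusted threshold, so these shares do not hold for a lone change. In the data Tmem182, at 1.86-fold with an unadjusted p of 2.0e-05 by limma, had an adjusted p of 0.915.

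A total of 38 gene lists were tested with limma's camera, which asks whether the members of a list changed more in one direction than the other genes. The preset correlation between genes was 0.01, and p was adjusted over the lists. The same test with an estimated correlation and fry, which asks whether members move one way on balance, were the alternatives. In 10 simulated draws with 1 list shifted by 0.15 on the log2 scale, camera with the preset correlation called the shifted list in 10 draws, camera with the estimated correlation in 0 and fry in 1. The simulated noise was independent between probe sets, so these draws cannot show how the preset does on correlated genes. In the data the estimated correlation reached 0.91, in the G2/M and mitosis list. Of 810 genes in the lists, 720 were measured.

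The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule takes in each direction 12 genes with 1 probe set each. Places go first to probe sets past adjusted p 0.05, and places left go to the smallest unadjusted p among single-gene probe sets with one direction in all 3 pairs, an absolute log2 change of at least 0.3 and a mean level in the higher of the 2 groups at or above 4.84, the median probe set. The rule adds the 2 members of each list with the smallest unadjusted p and 20 chosen genes, of which 18 were measured. Rbm3 and Gapdh have no single-gene probe set here. Alternatives were a fit with no block, a random block, quantile normalization or median centring of the log2 values, a filter on level, an intensity trend or robust prior, array weights, the mean of all probe sets of a gene, and leaving out each experiment.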

Results

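Mouse mesenchymal stem cells from a commercial source were grown in medium to which rosiglitazone (1 µM), insulin (5 µg/ml), the phosphodiesterase inhibitor IBMX (100 µM) and dexamethasone (1 µM), an adipogenic mix, were added again 48 h before exposure. Cultures were exposed for 2 h to pulsed broadband terahertz radiation, which lies between microwaves and infrared light, with 35 fs pulses centred near 10 THz, a repetition rate of 1 kHz and an average power density of 1 mW/cm2. A control culture stood beside the exposed one, and both were held at 26 to 27 °C. The data are 3 irradiated and 3 control arrays, 1 of each from each of 3 independent experiments. The study asked which transcripts differ between an irradiated culture and its own control. Differences below are irradiated minus control on the log2 scale, with the SE of limma's fit and n = 3 pairs.

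The cultures carried high levels of several fat-cell transcripts in both arms, and also of macrophage and leukocyte transcripts. Fabp4, the fatty acid carrier of adipocytes, averaged 14.45 ± 0.04 (SD, n = 3) in controls and 14.37 ± 0.02 (SD, n = 3) in irradiated cultures. These levels lie near 14.57, the highest value on any array. Adiponectin (Adipoq) averaged 13.83 ± 0.13 (SD, n = 3) and 13.69 ± 0.06 (SD, n = 3). Lipoprotein lipase (Lpl) averaged 13.71 in controls and 13.69 in irradiated cultures.

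No single transcript passed the test between irradiated and control cultures. The lowest p belonged to Tmem182, which encodes a transmembrane protein, with a difference of -0.89 ± 0.08 and pair differences of -0.84, -0.88 and -0.96, and an adjusted p of 0.915 by limma. Next on the lower side were Mlxipl, the glucose-responsive activator of lipid synthesis genes also called ChREBP (-0.55 ± 0.08), and Hcar1, the lactate receptor of fat cells (-0.56 ± 0.08). The fatty acid receptor Ffar4 (-0.53 ± 0.09), the peroxisomal fatty acid transporter Abcd2 (-0.49 ± 0.08), Adhfe1 (-0.49 ± 0.07) and the amino acid transporter Slc36a2 (-0.66 ± 0.12) were also among the 12 genes that the rule took on this side. On the higher side the rule took Zfp24, a zinc finger transcription factor (0.54 ± 0.08), the thiamine transporter Slc19a2 (0.46 ± 0.09), Col18a1, the collagen that yields endostatin (0.43 ± 0.08), and the mitotic kinase gene Mastl (0.39 ± 0.08).

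The other genes taken on the higher side were Garem1, Crebzf, Wdr86, Ankrd10, Slco4a1, Zfp287, Slc25a13 and Chtf18, and the 12 ranged from 0.34 to 0.54. Slco4a1 was taken with a probe set at 0.38, and another of its probe sets was at 1.23 ± 0.32, with pair differences of 0.21, 1.42 and 2.06. The other genes on the lower side were St3gal6, Prxl2a, Ndrg2, B3galt1 and Rnase2a, and the 12 ranged from -1.04 to -0.42. Rnase2a (-1.04 ± 0.16) belongs to a family of near-identical ribonuclease genes, so its value is uncertain. Adjusted p by limma was between 0.915 and 0.929 for all 24. For 6 of the 12 genes on the higher side and 2 of the 12 on the lower side, another probe set of the gene had the opposite sign. These were Zfp24, Slc19a2, Mastl, Crebzf, Ankrd10 and Zfp287 on the higher side, and Prxl2a and B3galt1 on the lower. The largest change of any probe set, in Car3, was not taken by the rule. It was at -1.28, with pair differences of -0.12, -2.45 and -1.26 (limma adjusted p = 0.929).

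**Figure D1:**
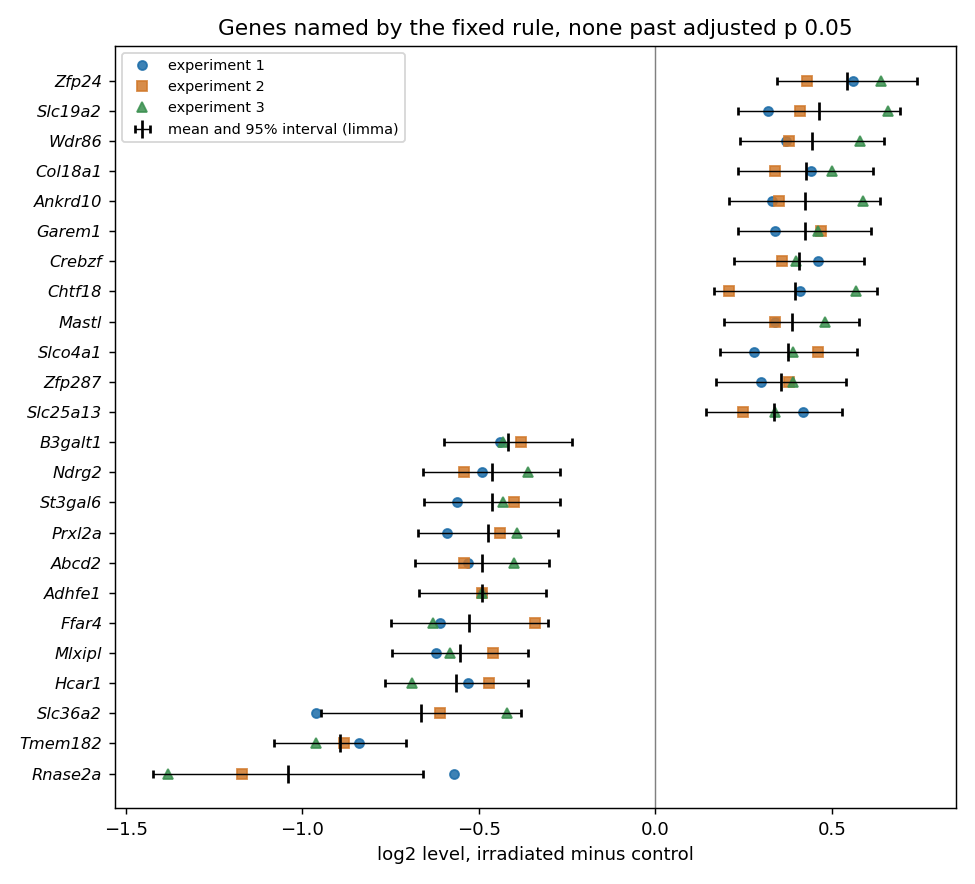
Log2 level of each irradiated culture minus its control (x axis) for the 24 genes named by the rule (y axis), with 1 symbol per experiment and black bars for the mean and its 95% interval from limma. Each gene has one sign in all 3 pairs because the rule required it, and adjusted p lay between 0.915 and 0.929.

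By limma with the experiment as a block, 0 of 45037 probe sets passed adjusted p 0.05, and 2237 had an unadjusted p under 0.05, of which 1166 were higher and 1071 lower, where chance alone gives 2251.85. All other limma settings also gave 0. The interval of the change lay inside 1.5-fold in both directions for 97.2% of probe sets and inside 2-fold for 99.9%. Changes of the 3 experiments correlated across probe sets with r of 0.012, 0.028 and 0.0024, with Spearman's rho of 0.0078, 0.022 and 0.0051, and genes are not independent replicates in these values. One direction in all 3 pairs was seen in 23.8% of all probe sets, and in 25.9% without the 3645 that have a pair difference of exactly 0 after rounding, where chance gives 25%. A change of at least 1.5-fold in the mean with unadjusted p under 0.01 and one direction in every pair was seen in 19 probe sets, 6 higher and 13 lower. Of these 19, 13 lay at or above the median level. The count was 35 without replicate 2, and 12 when the fit was repeated on probe sets at or above that level alone. An exact sign-flip test on 3 pairs cannot give a two-sided p under 0.25.

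Genes of fat storage were lower in irradiated cultures as a group. Of 29 measured members of the adipocyte and lipid droplet list, 28 had a negative and 1 a positive difference, with a median of -0.15 and pair medians of -0.18, -0.23 and -0.11. The list passed with the preset correlation (camera, adjusted p = 4.5e-13), and not with an estimated one (adjusted p = 0.70 with an estimated correlation). That estimate was 0.07, and unadjusted p was 0.036 by camera with it and 0.015 by fry (fry adjusted p = 0.42). In the 10 simulated draws camera with an estimated correlation called a list shifted by 0.15 in 0 and fry in 1. A miss by these tests therefore cannot decide whether a list changed by this much. None of the members passed over all genes, and 7 passed when p was adjusted over the list alone, all with negative differences. These were Cidec, which enlarges lipid droplets (-0.48 ± 0.09), the droplet coat gene Plin4 (-0.41 ± 0.09), hormone-sensitive lipase Lipe (-0.35 ± 0.08), the triglyceride synthesis enzyme Agpat2 (-0.44 ± 0.11), the glycerol channel Aqp7 (-0.50 ± 0.11), Adig (-0.65 ± 0.14) and resistin (Retn, -0.32 ± 0.08). Pparg and Cebpa, the regulators of the fat-cell program, were both at -0.13 ± 0.09, and neither passed.

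Other lists of fat metabolism had the same sign. In fatty acid and triglyceride synthesis, 13 of 17 members were negative and 0 passed over all genes or adjusted over the list alone, with a median of -0.14. Fatty acid synthase (Fasn) was at -0.36 ± 0.11. The list passed with the preset correlation (adjusted p = 0.00046; adjusted p = 0.70 with an estimated correlation). It shares 2 members with the adipocyte list, and its median was -0.085 without replicate 3. In fatty acid oxidation, 12 of 15 members were negative with a median of -0.10, and the list passed with the preset correlation (adjusted p = 0.0010; adjusted p = 0.70 with an estimated correlation). Of its members 0 passed over all genes and 1, the peroxisomal enzyme gene Ehhadh (-0.39 ± 0.08), passed adjusted over the list alone. Carnitine palmitoyltransferase Cpt2 was at -0.30 ± 0.08, and the list median was -0.055 without replicate 1. In the mitochondrial respiratory chain list 26 of 31 members were negative and 0 passed, with a median of -0.05 and an adjusted p of 0.0074 with the preset correlation (adjusted p = 0.70 with an estimated correlation). That call was lost without replicate 1 (median -0.02, adjusted p = 0.18) and without replicate 2 (median -0.04, adjusted p = 0.056), and without replicate 3 the median was -0.085 (adjusted p = 0.00031).

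Cell division lists had positive median differences, mostly from 1 experiment. All 28 measured members of the G2/M and mitosis list had positive differences, with a median of 0.23, and 0 passed over all genes or adjusted over the list alone. Aurora kinase A (Aurka) was at 0.27 ± 0.09, the spindle checkpoint gene Bub1b at 0.27 ± 0.09 and the proliferation marker Mki67 at 0.29. Pair medians were 0.065, 0.055 and 0.495. The list passed with the preset correlation (adjusted p = 3.3e-12; adjusted p = 0.70 with an estimated correlation) and its median was 0.07 without replicate 3 (adjusted p = 0.0041). Its estimated correlation was 0.91 against the preset 0.01, and camera's unadjusted p with the estimate was 0.24. In the G1/S and DNA replication list 23 of 24 members were positive and 0 passed, with a median of 0.15 and an adjusted p of 7.1e-06 with the preset correlation (adjusted p = 0.70 with an estimated correlation). The pair medians of this list were 0, 0.065 and 0.3, and without replicate 3 its median was 0.03 (adjusted p = 0.28). Control culture 3 had the highest mean of the hybridization spike-in controls, 11.63 against 11.06 to 11.25 on the other 5 arrays. The 3' minus 5' value of the Actb control probe sets was 0.72 in control culture 3 and 0.62 in irradiated culture 3, while the arms of the other experiments differed by at most 0.01.

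No heat shock gene passed the test between irradiated and control cultures. The inducible chaperone Hspa1a was at -0.07 with a 95% interval from -0.36 to 0.23, Hspa1b at -0.08, Hsph1 at -0.13 and Dnajb1 at -0.12. The interval lay inside 2-fold for all 22 measured members of the heat shock and chaperone list and inside 1.5-fold for 20. Of these members 18 were negative and 0 passed, and the list passed with the preset correlation (median -0.07, adjusted p = 0.028; adjusted p = 0.70 with an estimated correlation). Its pair medians were -0.01, 0.045 and -0.195, and the median was 0.025 without replicate 3 (adjusted p = 0.67) and -0.105 without replicate 2 (adjusted p = 0.0031). The list mean was 11.23 in control culture 3, the array with the highest spike-in signal, and 10.95 in irradiated culture 3. Cirbp, a cold-inducible RNA-binding protein gene, was at -0.17 ± 0.08, and the 6 measured cold-inducible genes had a median of -0.065 and did not pass.

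Oxidative stress, circadian clock and endoplasmic reticulum stress genes had small negative medians. They were -0.06 for oxidative stress (16 of 22 members negative, adjusted p = 0.028), -0.06 for the circadian clock (13 of 17, adjusted p = 0.028) and -0.03 for endoplasmic reticulum stress (19 of 25, adjusted p = 0.049), all with the preset correlation and with 0 members past the test. For each of them adjusted p = 0.70 with an estimated correlation. With no block, adjusted p was 0.17, 0.15 and 0.22, and for the heat shock list 0.21. Quantile normalization ended the calls for heat shock, oxidative stress and endoplasmic reticulum stress (adjusted p = 0.076, 0.080 and 0.13), and array weights ended these and the circadian clock's (adjusted p = 0.16 for heat shock and 0.079 for the others). With the mean of probe sets, adjusted p was 0.080 for heat shock, 0.076 for oxidative stress and 0.077 for the circadian clock. Without replicate 3 the medians were -0.03, -0.01 and -0.02 (adjusted p = 0.65, 0.68 and 0.44), and without replicate 1 oxidative stress and endoplasmic reticulum stress had medians of -0.08 and -0.055, both with an adjusted p of 0.075. Without replicate 2 the oxidative stress median was -0.10 (adjusted p = 0.0048), and with median centring that of endoplasmic reticulum stress was -0.05 (adjusted p = 0.038). Heme oxygenase Hmox1 was at -0.13 ± 0.09, the damage-induced cell cycle inhibitor Cdkn1a at -0.08 ± 0.08, and the early response genes Fos at -0.13 ± 0.11 and Egr1 at 0.04 ± 0.08, none past the test. Medians of -0.02 for p53 and DNA damage and -0.03 for immediate early genes did not pass, though without replicate 3 the p53 list did (median -0.04, adjusted p = 0.0497).

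Actin cytoskeleton and SRF target genes had a median of 0.09, with 22 of 24 members positive and 0 past the test. The list passed with the preset correlation (adjusted p = 0.0036; adjusted p = 0.70 with an estimated correlation). Its pair medians were 0.265, 0.02 and -0.01, so the shift lay in experiment 1. Tagln was at 0.28 ± 0.15 and Acta2 at 0.21 ± 0.11. Without replicate 1 the actin list median was 0.01 (adjusted p = 0.95). Ribosome biogenesis genes had a median of 0.06, with 21 of 24 positive and 0 past the test (adjusted p = 0.0049 with the preset correlation; adjusted p = 0.70 with an estimated correlation), and an adjusted p of 0.15 without replicate 3. Of 38 lists, 13 passed with the preset correlation, 5 higher and 8 lower, and 0 with an estimated correlation or by fry. The adjustment gave all 13 the same 0.70 with an estimated correlation. Their unadjusted p by that test ranged from 0.036 for the adipocyte list to 0.46 for heat shock.

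Markers of 8 cell types other than fat cells had medians between -0.04 and 0.07. The 14 macrophage and leukocyte markers had a median of 0.07, with 12 positive and 0 past the test (adjusted p = 0.015 with the preset correlation; adjusted p = 0.70 with an estimated correlation), and Cd14 was at 0.27 ± 0.09. Without replicate 3 this median was 0.035 (adjusted p = 0.28), and with the mean of probe sets adjusted p was 0.053. The other 7 cell type lists did not pass, with medians of 0.02 for mesenchymal stem cell, 0.07 for endothelial, 0.03 for skeletal muscle, -0.04 for chondrocyte, -0.02 for neuronal, 0.0017 for epithelial and -0.0017 for osteoblast markers. The endothelial list passed with the mean of probe sets (median 0.10, adjusted p = 0.022) and without replicate 3 (median 0.11, adjusted p = 0.020).

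The remaining lists did not pass, though without replicate 2 the cholesterol (median -0.095, adjusted p = 0.0048), cAMP (median -0.16, adjusted p = 0.0089) and interferon (median 0.09, adjusted p = 0.0066) lists did. Without replicate 3 these medians were 0.00, 0.03 and -0.005, and without replicate 1 they were -0.025, -0.19 and 0.015, none past the test. Medians were -0.04 for cholesterol synthesis, -0.08 for cAMP and CREB targets, 0.03 for interferon response, -0.03 for hypoxia and glycolysis, -0.05 for glucocorticoid targets, 0.02 for cytosolic ribosomal proteins and -0.035 for insulin and IGF signalling. They were -0.0033 for autophagy and lysosome, -0.02 for NF-kB and inflammatory cytokines, -0.0067 for extracellular matrix, 0.10 for 5 replication-dependent histone genes, 0.0033 for TGF-beta and BMP targets, 0.01 for Wnt signalling, 0.00 for apoptosis regulators and 0.01 for ion channels and mechanosensors. The sign of the median for ribosomal proteins, TGF-beta and BMP targets, Wnt signalling, ion channels, epithelial and osteoblast markers, and autophagy flipped under quantile normalization or median centring. The median, the mean and camera's direction differed in sign for NF-kB, Wnt signalling, apoptosis regulators, neuronal and osteoblast markers.

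**Figure D2:**
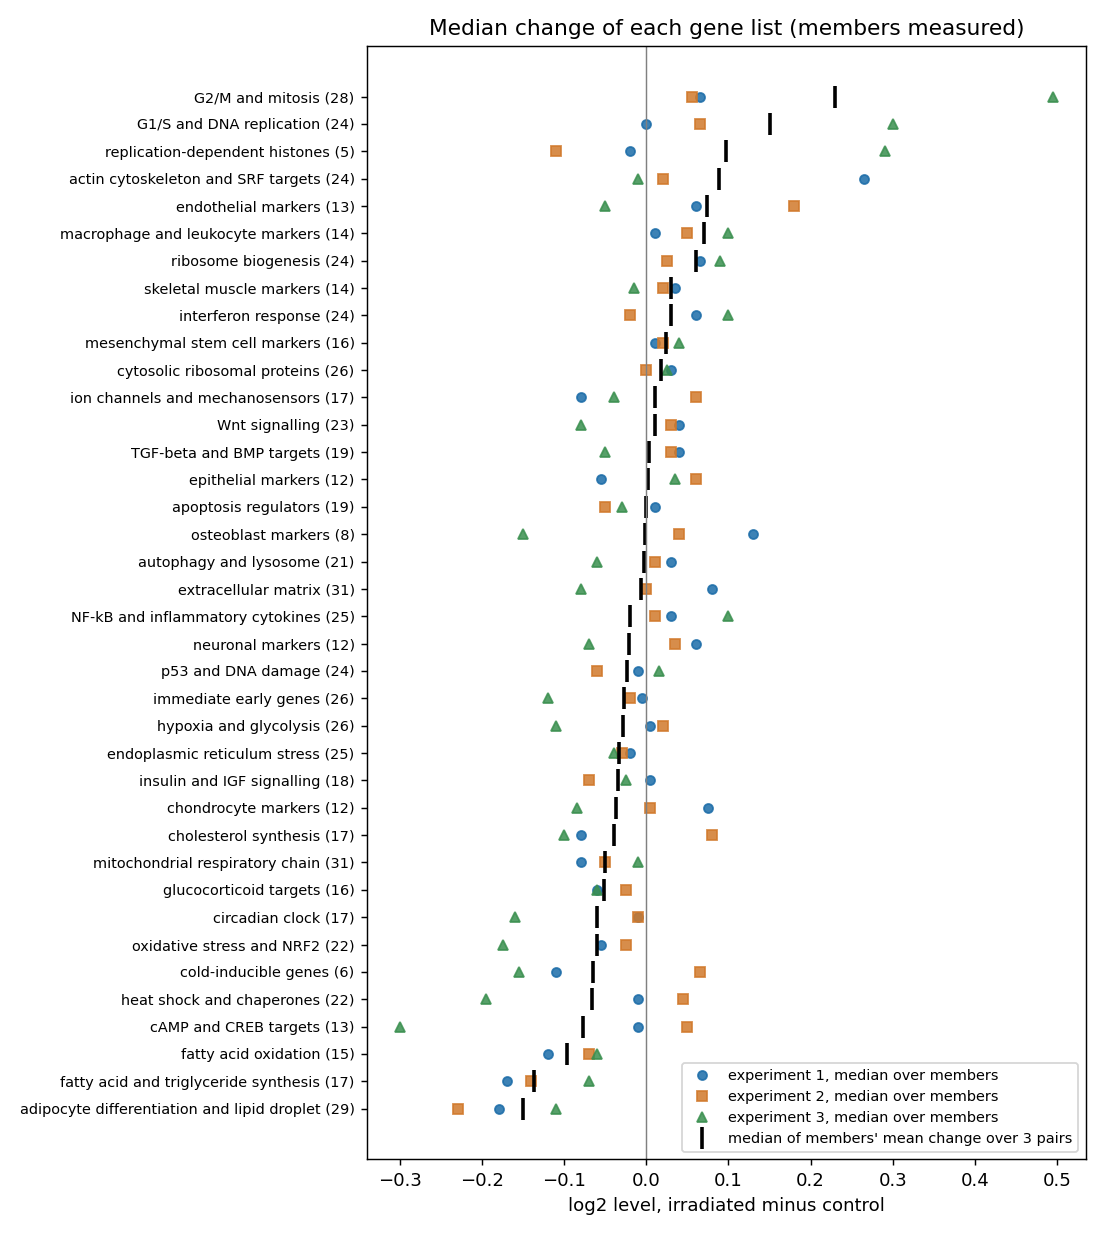
Median log2 difference, irradiated minus control, over the members of each of 38 gene lists (y axis, number of measured members in parentheses), per experiment (symbols) and for the mean over the 3 pairs (black bars). The adipocyte list lies at -0.18, -0.23 and -0.11 in the 3 experiments, while the G2/M list lies at 0.065, 0.055 and 0.495.

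Levels of Hspa1a and Fos differed more between experiments than between the arms of one experiment. Hspa1a stood at 5.71 in the control and 5.63 in the irradiated culture of experiment 1, at 8.83 and 9.06 in experiment 2, and at 12.7 and 12.35 in experiment 3. Fos stood at 11.09 and 10.72, at 12.77 and 12.65, and at 13.13 and 13.22. Adipoq lay between 13.62 and 13.94 on the 6 arrays. The 3' minus 5' value of the Gapdh control probe sets, a sign of RNA integrity, was 0.19 and 0.23 in experiment 1 and between -0.05 and -0.01 in experiments 2 and 3. Over all probe sets, experiment took 65.5% of the sum of squares, irradiation 11.8% and the residual 22.7%, which per degree of freedom is 955.45 for irradiation and 915.73 for the residual.

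**Figure D3:**
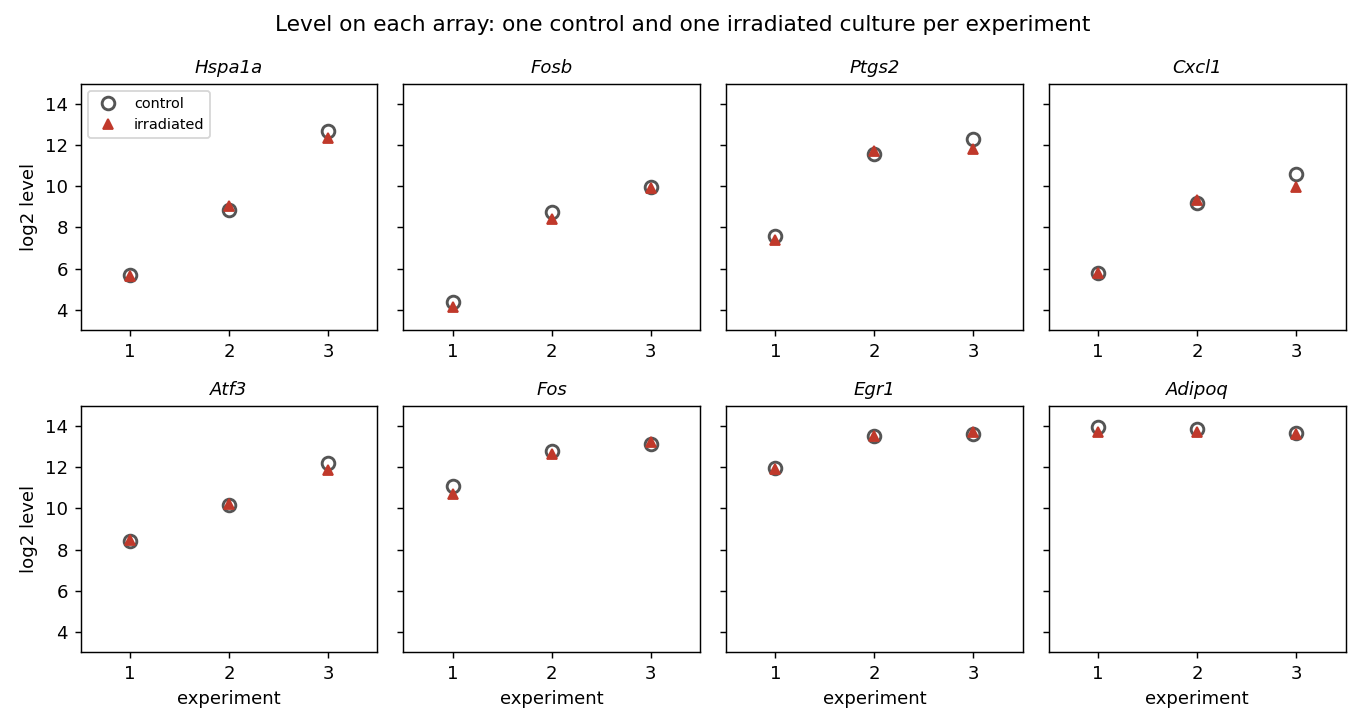
Log2 level (y axis) of 8 transcripts on each of the 6 arrays, with open circles for control and triangles for irradiated cultures, by experiment (x axis). Fosb, Ptgs2, Cxcl1 and Atf3 were chosen after their values were seen. Hspa1a lies between 5.63 and 12.7 across experiments, while the arms of one experiment differ by -0.08, 0.23 and -0.35.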

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

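All alternatives were planned. In every limma setting 0 probe sets passed adjusted p 0.05. The count with unadjusted p under 0.05 was 2237, against 1297 with no replicate block, where experiments add to the residual, and 1146 among probe sets at or above the median level, where fewer are tested. The count with unadjusted p under 0.01 and a mean change of at least 1.5-fold in one direction in every pair was 19, against 12 in the fit with that filter, and 15 to 35 when one replicate was left out. The mean correlation of changes between experiments, 0.014, was 0.033 with the filter, and the cause was not tested. Of 38 lists 13 passed, against 0 with an estimated correlation, 0 by fry and 8 to 15 when one replicate was left out. The 8 lists without replicate 3 hold 6 of the 13, and the 15 without replicate 2 hold 12. The other settings gave 9 to 13 lists, with 9 under no block, all among the 13 except 1 of the 10 with the mean of probe sets. The heat shock median ranged from -0.105 without replicate 2 to 0.025 without replicate 3, where it turned. The intensity trend and robust prior do not enter camera, so their 76 list values could not move. Of 415 list values in the other settings, 356 kept their side of the threshold, 52 lost the call with the same sign, 1 with another and 6 gained one, and 40 medians of lists without a call had another sign, 21 of them with a replicate left out. None of the 1262 values of named genes passed, and their smallest adjusted p was 0.064, with an intensity trend. The list test was not run with a random block, which camera does not take. Apart from the losses named, with no block, of the calls for heat shock, oxidative stress, circadian clock and endoplasmic reticulum stress, the block changed no call. Background correction could not be varied, so its effect on dim probe sets is unknown.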

Other observations

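The tests between experiments, the test of the adipocyte share, the splits for the adipocyte list, the test of control culture 3 and the RNA integrity test were chosen only after the result was seen.

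Early response genes were higher in both cultures of experiments 2 and 3 than in those of experiment 1. In limma's fit, 1374 probe sets passed adjusted p 0.05 between experiments 3 and 1 (841 higher in 3, 533 lower), 234 between 2 and 1 (213 higher, 21 lower) and 16 between 3 and 2 (16 higher). Each contrast compares 2 arrays with 2 arrays. Above experiment 1, experiment 3 was higher by 6.85 ± 0.15 (SE) in log2 for the heat-inducible chaperone Hspa1a, by 5.70 ± 0.11 for the transcription factor Fosb, by 4.59 ± 0.16 for the prostaglandin synthase Ptgs2 and by 4.50 ± 0.18 for the neutrophil chemokine Cxcl1, with adjusted p of 0.00011, 0.00011, 0.00029 and 0.00045. Of 26 immediate early genes 20 were higher and 1 was lower past the test, with a list median of 2.20, and of 22 heat shock genes 9 were higher and 0 lower, with a median of 0.44. These lists passed with the preset correlation (adjusted p = 4.4e-24 and 1.8e-12), and not otherwise (adjusted p = 0.27 and 0.42 with an estimated correlation). Between experiments 2 and 1, 19 immediate early and 3 heat shock genes were higher past the test. By camera the adjusted p of these lists was 8.4e-32 and 6.9e-06 with the preset correlation, and 0.21 and 0.68 with an estimated one. Between 3 and 2 there were 2 of each. There camera's adjusted p was 3.1e-13 and 4.5e-13 with the preset correlation, and 0.49 and 0.69 with an estimated one.

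Experiment 3 also stood above experiment 1 in 9 of 24 p53 and DNA damage genes, 8 of 25 NF-kB and cytokine genes, 7 of 13 cAMP and CREB targets and 6 of 22 oxidative stress genes, with 0 lower in each. By camera the adjusted p of these lists was 1.4e-05, 9.8e-05, 1.9e-06 and 2.0e-05 with the preset correlation, and 0.35, 0.35, 0.36 and 0.35 with an estimated one. Between experiments 3 and 2 the counts were 0, 0, 1 and 0. Fosb is in both the cAMP and the immediate early list. Overlap among these lists was not counted, so they may hold some of the same genes. Other lists had lower medians in experiment 3 than in experiment 1. These were G2/M and mitosis (-0.37), the respiratory chain (-0.135) and G1/S (-0.21), each with 0 members lower past the test. G1/S had 2 members higher past it. By camera their adjusted p was 1.9e-06, 0.00081 and 0.031 with the preset correlation, and 0.60, 0.60 and 0.73 with an estimated one. The G1/S mean was 8.27 in control culture 3 and 8.57 in control culture 1, but 8.61 and 8.58 in irradiated cultures 3 and 1. So this list was lower in the control arm only. In the same order the G2/M means were 7.42, 7.98, 7.93 and 8.06, and those of the respiratory chain 11.66, 11.83, 11.66 and 11.75. The most abundant probe set of the fat-cell gene Fabp4 lay between 14.36 and 14.48, near the highest value on any array, 14.57, so its level shows little about a difference between experiments. Another of the 4 probe sets of Fabp4 was lower in experiment 3 than in experiment 1, at -1.96 ± 0.12 (limma adjusted p = 0.0014). The adipocyte list had a median of -0.175 in this contrast, with 2 members higher and 3 lower past the test. It did not pass by camera (adjusted p = 0.11 with the preset correlation, 0.60 with an estimated one).

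A first pattern is the difference of early response and heat shock genes between experiments, in both arms. Of 10000 random lists matched on level, 0% had a difference between experiments 3 and 1 as high as the 2.20 of the immediate early list, which argues against a bias with signal level. A difference in RNA integrity between experiments 2 and 3 is argued against by the 3' minus 5' value of the Gapdh control probe sets, which differed by 0.02, within the largest difference of 0.04 between arms, while the heat shock list mean differed by 0.66. The Actb value differed by 0.055, where its arms differed by up to 0.10, and between irradiated cultures 3 and 2 alone by 0.01, while the heat shock list mean differed by 0.498. Experiment 1 had a higher Gapdh value (0.19 and 0.23), so for that experiment RNA integrity stays open, as does handling before lysis, and no biological explanation was tested.

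Another pattern is the lower level of the adipocyte list in irradiated cultures. Of 10000 random lists matched on level, 0% had a median as low as -0.15, which argues against a bias with signal level. A lower share of adipocytes in the irradiated dish may account for it and cannot be told apart here from a change within cells. The macrophage median minus the mesenchymal median was 0.03 (SD 0.03 over 3 pairs), so these other cell types did not move apart by more than 2 SD. That difference does not measure the adipocyte share, so it cannot decide. Members ranged from Lep at 0.02 to Adig at -0.65, and whether a lower share would give so uneven a fall was not tested. Lep had a control level of 2.8, under the lower quartile of every array, so its value shows little. Fabp4 (-0.08), at 14.45 in controls, lay near the highest value on any array, so part of the unevenness may come from the range of the arrays. The 10 splits of the 6 arrays are too few for a share under 0.05, with a real median of size 0.15, 5 splits as large, the real one included, and a highest other of 0.23, or 0.13 among the splits that part all 3 pairs. The others as large part only 1 pair. With the block they repeat the real difference of that pair, of size 0.18 in pair 1 and 0.23 in pair 2, so they are not comparable with 0.15. The 4 splits that part all 3 pairs are too few to decide. Irradiation itself stays among the open explanations.

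The last pattern is the difference of mitotic genes between the cultures of experiment 3. Of 10000 random lists matched on level, 0% had a median in pair 3 as high as 0.495, which argues against a bias with signal level. The list mean was 7.93 in irradiated culture 3, within the range of the other arrays, and 7.42 in control culture 3, 0.399 under the nearest other array, against a range of 0.246 over the other 5 arrays. This is consistent with a difference of control culture 3 itself, which also had the highest spike-in signal, the lowest correlation with another array (0.9898, with irradiated culture 1) and an Actb 3' minus 5' value of 0.72 against 0.62 in its pair. Whether this control divided less or its RNA differed in quality was not tested, and irradiation is not excluded as a part of it, since the medians in pairs 1 and 2 were 0.065 and 0.055.

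With 6 arrays the 10 splits are too few for a share under 0.05 for any count. With 0 probe sets past adjusted p 0.05, the highest other split also gave 0, as did 10 of 10. For unadjusted p under 0.05 the real split gave 2237 probe sets and the highest other 5246, or 2252 among the splits that part all 3 pairs, and 4 splits gave as many. For the count of 19 with a size floor the highest other was 824, or 12 among those splits, and 7 gave as many. For the 13 gene lists the highest other was 10, or 9 among those splits, and 1 split, the real one, gave as many. Splits that do not part all 3 pairs part only 1, where one direction in every pair holds by itself. Their size-floor counts are thus not comparable with 19. With the block, those that rest on the same pair are also the same test. The splits with 5246 and 824 keep the other two pairs whole, so that with the block they rest on pair 3 alone, whose changes had an SD of 0.237 against 0.186 and 0.181, so these counts reflect the spread within that pair.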
